A study of Mus musculus with 16 samples.

How the data were processed

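Lung cells of mice were barcoded with split-pool combinatorial indexing (Parse Evercode WT v3) after sorting of live cells, per the labels' protocols. The 16 deposited GEO entries are sublibraries, which are technical splits of 1 pool of cells, and each held cells of all 15 samples. The deposited matrix holds raw transcript counts per gene and cell, which the authors did not normalise, and its cell totals equalled the deposited transcript count for 99.0% of cells. The deposited table gives for each cell its sample, treatment, seeding state, cell type and the percent of mitochondrially encoded transcripts, which was recomputed from the matrix. Seurat 5.3.0 and the mouse build mm39 are named in the submitters' processing notes. The aligner, the counting tool and the filters on cells are not given in the sources used here. The lowest number of genes in a cell was 301 and the highest mitochondrial percent 9.99. Depth ran from 10003796 to 32580698 transcripts per sample, and the median cell held 2307 transcripts and 965 genes.

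The seeding state is written as IV in the deposited table. It was read as PDAC cells seeded, since 308 of the 312 annotated cancer cells came from samples that carry it. Groups were taken from the deposited table. Counts were summed per sample and cell type, and a sample with under 20 cells of a type left that type's fit. A type needed 2 samples in each group compared. Genes were filtered with filterByExpr, libraries were scaled by TMM, and all 6 groups were fitted together with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method within each cell type and comparison, with a threshold of 0.05. There were 5 comparisons and 2 interactions, which test the difference between a drug's effects with and without PDAC cells. The same model on cell numbers tested cell type shares, adjusted over types, with two-sided exact permutation tests beside it. Those cannot give a p under 0.1 with 3 against 3 or 2 against 3 samples, or under 0.333 with 2 against 2.

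Gene lists fixed in advance were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over lists and types. A list was tested in a type where at least 5 of its genes passed the filter, which left 27 lists. Estimated correlations and the rotation test fry were run beside camera. The fry test asks whether a list's genes move one way on balance and does not compare the list with other genes. Counts of list members are given over all genes tested and adjusted over the list alone. The comparisons, tests, gene lists and most alternatives were set before the data were examined.

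Named genes follow a fixed rule. In the 3 types with the most calls of a comparison, the 4 largest rises and 4 largest falls past the threshold with a mean of at least 20 CPM are taken. Predicted genes, ribosomal and mitochondrially encoded genes and variable genes of immune receptors are left out there. Members of the NPY and adrenergic lists at 20 CPM or more are taken too, with up to 4 members of each other list past its threshold. Where fewer than 8 genes pass in a comparison, the 5 with the smallest p are taken, and those that did not pass are said not to. Counts of the genes named by the rule cover all genes it takes by size or by p, while the text gives values for a part of its genes, picked after their values were seen. Genes outside the rule are marked in the text as chosen after their values were seen. CPM means and SDs are over samples, scaled by TMM. Shares of single samples carry 95% Clopper-Pearson intervals, and a count of 0 is bounded by a floor of 3 counts. The ratio of pooled counts that rests on a single vehicle transcript carries an exact binomial counting interval.

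The procedure was tested on simulated data built from these counts, with known changes. For 2-fold and 4-fold changes, 52.0% and 92.9% were recovered in alveolar fibroblasts at 3 against 3 samples (BIBO3304), and 36.6% and 88.3% in dendritic cells (6-OHDA). At 2 against 2 samples, 20.7% and 84.5% were recovered in interstitial macrophages for 6-OHDA and 14.6% and 85.7% for BIBO3304. The percent of unchanged genes among simulated calls was 2.5 to 9.42. Cell type annotations were checked with fixed marker lists.

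Alternatives were RLE size factors, no gene filter, a minimum of 50 cells, a fit of the compared groups alone, a term for the sample number (for gene lists chosen after seeing the data), DESeq2 1.42.0, and leaving out each sample in turn. Scrublet, run with scanpy 1.11.5 at an expected rate of 0.05, called 32 cells as doublets, too few to test the effect of leaving doublets out. Leaving out the top 5% of its scores per sublibrary (3803 cells) was chosen after seeing the data. Permutation tests were run in R 4.3.3. Count matrices were read and summed with scipy 1.17.1 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. An annotation of an older mouse build was used for the span of genes, matched by symbol for 96.4% of the genes tested, and no coordinate is printed. Subclustering of cell types, and read-level data, were not analysed here.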

Results

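Single-cell RNA sequencing was done on mouse lung cells after treatment with vehicle, 6-OHDA or BIBO3304, each without and with seeded pancreatic ductal adenocarcinoma (PDAC) cells. 6-OHDA is a toxin that enters sympathetic nerve terminals through the norepinephrine transporter and destroys them. BIBO3304 is an antagonist of NPY1R, a receptor for neuropeptide Y, which sympathetic neurons release. The deposited data held 80449 cells and 38003 genes in 15 samples. There were 3 samples each of vehicle, 6-OHDA and BIBO3304 without PDAC cells, and 2 samples each of vehicle, 6-OHDA and BIBO3304 with PDAC cells. The groups are called vehicle-PDAC, 6-OHDA-PDAC and BIBO3304-PDAC where PDAC cells were seeded. No source used here says whether the numbered samples are separate mice, so the p-values measure the spread between these samples. The groups held 21881 (vehicle), 11628 (6-OHDA), 13312 (BIBO3304), 15971 (vehicle-PDAC), 7454 (6-OHDA-PDAC) and 10203 (BIBO3304-PDAC) cells.

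Total transcripts in vehicle samples 1 to 3 were 21346701, 13309318 and 18800423. They were 12195761, 11020282 and 10003796 in 6-OHDA 1 to 3, and 15048517, 26555562 and 25185750 in BIBO3304 1 to 3. The vehicle-PDAC samples held 32580698 and 27639435 transcripts, the 6-OHDA-PDAC samples 14746383 and 13694977, and the BIBO3304-PDAC samples 18096496 and 10916216. Depth per cell differed between groups. The median number of transcripts per cell was 1640 to 1906 in vehicle samples, 2078 to 2223 in 6-OHDA samples and 2631 to 4846.5 in BIBO3304 samples. With PDAC cells it was 2411 to 3411 under vehicle, 2559 to 2729 under 6-OHDA and 1623 to 2417 under BIBO3304. Intervals and floors given below cover counting error only.

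The authors' annotation named 22 cell types. Alveolar macrophages were the most numerous with 23624 cells (29.4%), followed by alveolar fibroblasts with 14592 (18.1%) and general capillary endothelial cells with 8330 (10.4%). Interstitial macrophages numbered 3295 and monocytes 3872, and the smallest types were club cells (161), alveolar type 1 cells (191) and cancer cells (312). Fixed marker genes for alveolar type 1, alveolar type 2 and club cells were highest in the types of those names, by mean log2 excesses of 5.71, 5.57 and 5.98 over the other types. Venous and arterial endothelial markers were both highest in large-vessel endothelial cells. Markers of conventional dendritic cells of the Cd209a and Clec10a kind were highest in the interstitial macrophages (excess 1.98) and next in the dendritic cells (1.68), so the interstitial macrophage type held a mixed signal.

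Of the 312 cancer cells, 308 came from samples with PDAC cells. 6-OHDA-PDAC 1 held 75 among 3955 cells (1.90%, 95% Clopper-Pearson interval 1.49 to 2.37) and 6-OHDA-PDAC 2 held 71 among 3499 (2.03%, 1.59 to 2.55). BIBO3304-PDAC 1 held 33 among 5466 (0.604%, 0.416 to 0.847) and BIBO3304-PDAC 2 held 73 among 4737 (1.54%, 1.21 to 1.93). Vehicle-PDAC 1 held 56 among 6814 (0.822%, 0.621 to 1.07). Vehicle-PDAC 2 held 0 among 9157, which allows a share of up to 0.0328%. It is labelled as seeded, but these counts leave open whether it received PDAC cells, and it is 1 of the 2 samples of the group behind every comparison with PDAC cells. Onecut2, a transcription factor gene, reached 112 CPM (counts scaled to a fixed library total) in cancer cells and at most 0.871 CPM in any other type. Spp1, which encodes osteopontin, reached 367 CPM in cancer cells against 84.6 CPM in alveolar macrophages. The share did not pass the test for 6-OHDA against vehicle with PDAC cells (log2 fold change 2.31 ± 0.986, SE, adjusted p = 0.167), nor for PDAC cells against none under vehicle (4.26 ± 1.35, adjusted p = 0.196).

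Without PDAC cells, 6-OHDA went with more monocytes and neutrophils and with fewer alveolar macrophages. Monocytes made up 8.395% ± 1.77 (SD, n = 3) of cells under 6-OHDA and 2.69% ± 1.07 (n = 3) under vehicle, a log2 fold change of 1.65 ± 0.377 (SE, adjusted p = 0.0102). Neutrophils made up 3.34% ± 0.766 against 1.39% ± 0.235 (1.26 ± 0.308, adjusted p = 0.0102). Alveolar macrophages made up 22.3% ± 1.93 against 38.1% ± 3.84 (-0.77 ± 0.216, adjusted p = 0.0202). That last call was lost without 6-OHDA 2 (adjusted p = 0.0986) or without 6-OHDA 3 (0.112). Under BIBO3304 alveolar macrophages made up 17.8% ± 1.94, a log2 fold change of -1.09 ± 0.217 (adjusted p = 0.00306), and club cells 0.0665% ± 0.0132 against 0.282% ± 0.155 (-2.00 ± 0.480, adjusted p = 0.00858), which rest on 2 to 4 club cells per BIBO3304 sample. The club cell call was lost without the top 5% of Scrublet scores (adjusted p = 0.0604), an alternative added after the data were seen. General capillary endothelial cells (16.4% against 8.54%) did not pass (0.94, adjusted p = 0.0592). In each of these calls all 3 treated samples lay on 1 side of all 3 vehicle samples, and exact permutation tests gave 0.1, the smallest two-sided value that 3 against 3 allows. A fall in 1 large type raises the shares of all others, since shares sum to 100%. Across the 22 types, 4 (6-OHDA) and 9 (BIBO3304) had an unadjusted p under 0.05.

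With PDAC cells, alveolar macrophages made up 13.96% ± 0.462 of cells under 6-OHDA and 37.6% ± 9.72 under vehicle (SD, n = 2 each), a log2 fold change of -1.43 ± 0.269 (SE, edgeR adjusted p = 0.00175). Interstitial macrophages rose to 11.4% ± 2.30 from 3.52% ± 0.482 (1.69 ± 0.428, adjusted p = 0.0117). Neutrophils rose to 3.11% ± 0.111 from 1.13% ± 0.306 (1.46 ± 0.381, adjusted p = 0.0117). The interstitial macrophage call was lost without 6-OHDA-PDAC 1 (adjusted p = 0.0729) or vehicle-PDAC 2 (0.0586), and the neutrophil call without 6-OHDA-PDAC 1 (0.0651) or vehicle-PDAC 1 (0.0813). Exact permutation tests gave 0.333, the smallest value that 2 against 2 allows. Under BIBO3304 with PDAC cells, 0 types passed by edgeR and 1 had an unadjusted p under 0.05, the interstitial macrophages (0.94, adjusted p = 0.556). For PDAC cells against none under vehicle, 0 types passed and 2 had an unadjusted p under 0.05. The count became 1 without vehicle-PDAC 2 for PDAC cells against none, and 1 without vehicle-PDAC 1 for BIBO3304 with PDAC cells. Shares by DESeq2 were not analysed here. Tests of whether a drug's effect on a share differed with PDAC cells passed for no type. The interstitial macrophage value was 1.24 for 6-OHDA (adjusted p = 0.782) and the club cell value 2.44 for BIBO3304 (adjusted p = 0.0768).

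**Figure D1:**
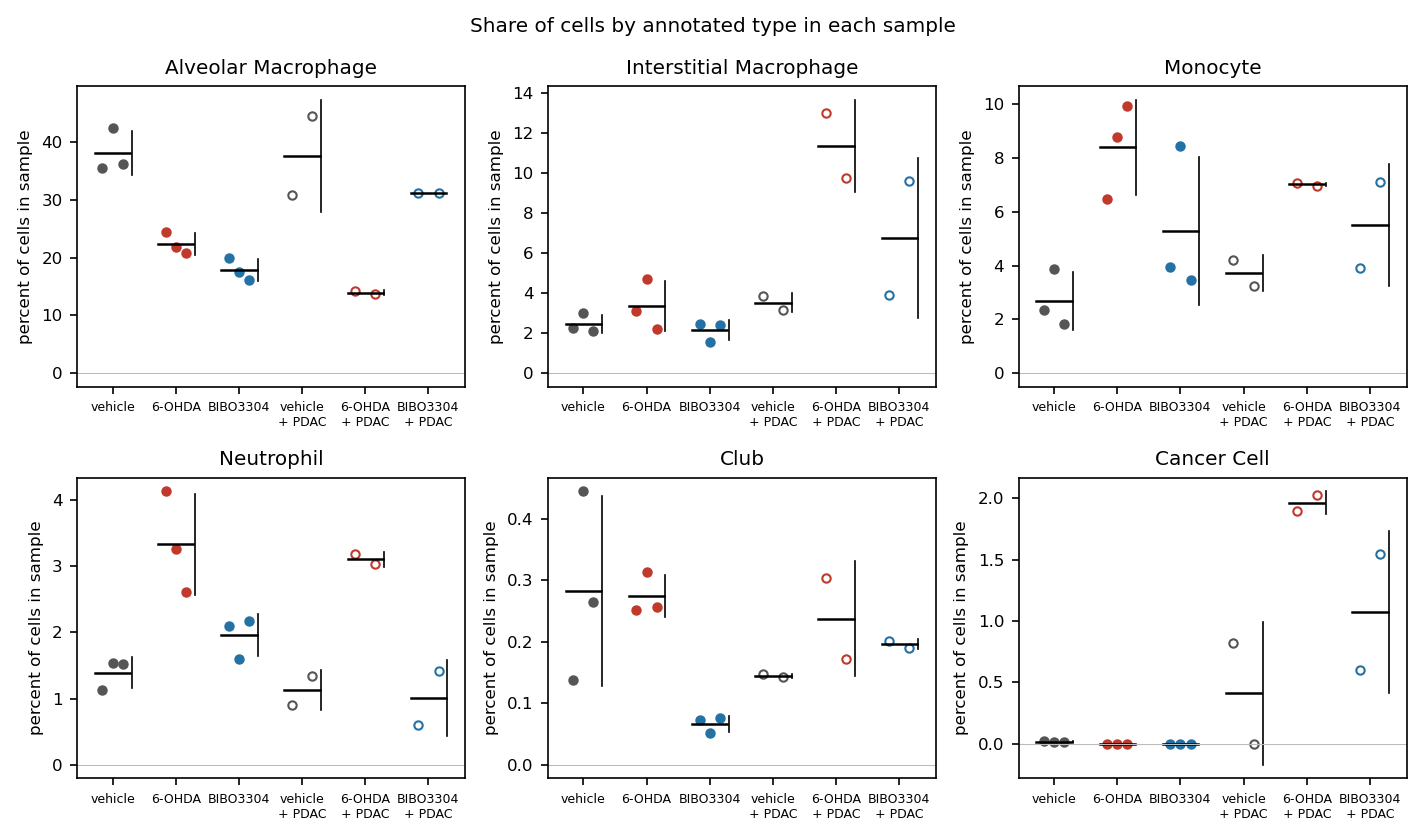
Percent of each sample's cells (y axis) in 6 cell types by group (x axis), with a point per sample, a line at the mean and a bar for the SD. Alveolar macrophages averaged 38.1% under vehicle, 22.3% under 6-OHDA and 17.8% under BIBO3304.

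The comparison of 6-OHDA with vehicle without PDAC cells asks what the toxin changes in lung cells. Loss of sympathetic terminals was not measured here. Slc6a2, the norepinephrine transporter gene, fell in large-vessel endothelial cells, from 599 ± 44.1 CPM (SD, n = 3) under vehicle to 124 ± 28.9 CPM (n = 3) under 6-OHDA. Its log2 fold change was -2.26 ± 0.235 (SE, adjusted p = 7.32e-07), with 54 of 439709 transcripts against 699 of 1211423, and each 6-OHDA sample (98.96 to 156 CPM) lay below each vehicle sample (549.5 to 635). In the same cells Clu, which encodes the chaperone clusterin, rose from 66.9 ± 15.5 to 222 ± 64.6 CPM (1.67 ± 0.290, adjusted p = 0.00819), and Lsamp and Col5a2 rose by log2 fold changes of 2.63 and 1.16. In dendritic cells Ccr9, a chemokine receptor gene of plasmacytoid dendritic cells, rose from 31.1 ± 11.2 to 144 ± 43.2 CPM (2.14 ± 0.346, adjusted p = 0.00374). Pacsin1 rose there by 2.25 ± 0.407 (104 ± 67.8 against 21.3 ± 5.92 CPM, adjusted p = 0.0077). Mir6236 fell by 2.06 ± 0.280 on the log2 scale (adjusted p = 0.000978). In general capillary cells the transcription factor gene Klf6 rose by 0.88 ± 0.166 (adjusted p = 0.0389), and Ccnd3, which encodes cyclin D3, changed by -1.72 ± 0.289 (145 ± 62.1 against 487 ± 105 CPM, adjusted p = 0.0291). The fixed markers of plasmacytoid dendritic cells, which include Ccr9, had a median log2 fold change of 1.14 within the dendritic cells (6 genes, 0.83 to 2.14, 3 of them called), and no marker of the other dendritic cell kinds was called. Under BIBO3304 without PDAC cells Ccr9 stood at 54.41 to 103.1 CPM there, against 21.84 to 43.55 CPM under vehicle, with 0 genes called in that type.

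Arg1, the arginase gene of alternatively activated macrophages, was seen as 37 of 1100284 transcripts in interstitial macrophages under 6-OHDA and 0 of 1179727 under vehicle, at least 13.2-fold higher with a floor of 3 transcripts over the vehicle group (adjusted p = 0.0298). The 6-OHDA samples held 5, 26 and 6 Arg1 transcripts. This gene, Pde3b and Adgre4 were chosen after their values were seen, as the 3 genes called in interstitial macrophages. Pde3b rose by 1.45 ± 0.249 (448 ± 85.0 against 162.5 ± 15.4 CPM) and Adgre4 by 1.84 ± 0.326 (117 ± 41.0 against 33.5 ± 11.95 CPM), each with an adjusted p of 0.0298. Without 1 sample the highest adjusted p was 0.217 for Arg1 and Pde3b (without vehicle 3) and 0.222 for Adgre4 (without vehicle 3). The Arg1 call was lost without any 1 sample but 6-OHDA 1. Pde3b was lost without 6-OHDA 3 or any 1 vehicle sample, and Adgre4 without 6-OHDA 2 or any 1 vehicle sample. Gsg1l rose in alveolar fibroblasts (1.70 ± 0.223, 46.5 ± 6.12 against 13.7 ± 4.02 CPM, adjusted p = 0.00543), a call lost without 6-OHDA 3 (0.0598). It too was chosen after its values were seen, as the 1 call in that type.

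In all, 76 genes passed in 9 of 19 cell types for 6-OHDA without PDAC cells, 57 higher and 19 lower among 113537 tests by edgeR. Dendritic cells held 43 of them, large-vessel endothelial cells 11 and general capillary cells 8. The count was 55, 25 and 87 without 6-OHDA 1, 2 and 3, and 4, 49 and 49 without vehicle 1, 2 and 3. Of the 24 genes named by the fixed rule, 15, 6 and 11 stayed past the threshold without 6-OHDA 1, 2 and 3, and 3, 14 and 13 without vehicle 1, 2 and 3. Slc6a2 in large-vessel endothelial cells and Mir6236 in dendritic cells stayed past it in every such fit. Klf6 was lost without 6-OHDA 2 (adjusted p = 0.131), 6-OHDA 3 (0.319), vehicle 1 (0.271) or vehicle 3 (0.139), and Ccnd3 in general capillary cells without 6-OHDA 2 (0.0882), 6-OHDA 3 (0.284) or vehicle 1 (0.245). Lsamp was lost without 6-OHDA 1 (0.27) or any 1 vehicle sample (0.0612 to 0.202), and Col5a2 without any 1 of the 6 (0.0522 to 0.155). Ccr9 was lost without 6-OHDA 2 (0.0522), Clu without vehicle 1 (0.119), and Pacsin1 without 6-OHDA 2 (0.102) or vehicle 1 (0.0764). Mir6236 was lower in 19 of 19 types and called in 6, and it was lower in 17 of 17 types under 6-OHDA with PDAC cells. In dendritic cells it stood at 8609 to 15370 CPM in vehicle samples. It was lower there under BIBO3304 too (5427 to 6744 CPM), and in vehicle-PDAC samples (5635 and 5418 CPM).

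Gene lists fixed in advance were tested under 6-OHDA without PDAC cells. Of 372 tests of a list in a type, 110 passed by camera with the preset correlation, 29 higher and 81 lower. With an estimated correlation 0 passed, the smallest adjusted p was 0.613 and 25 had an unadjusted p under 0.05. The directional test fry passed 2. By camera, heat shock genes were higher in 13 of 19 types, with a median of the type medians of 0.52 on the log2 scale. Hspa1b and Hsph1 carried the 4 calls among 228 tests of list members, in lymphatic endothelial cells (log2 fold changes 3.86 and 3.71) and mesothelial cells (2.32 and 2.31), and 42 tests passed when adjusted over the list alone. Each of the 4 calls was lost without 6-OHDA 3 (adjusted p = 0.501, 0.312, 0.541 and 0.541), vehicle 1 (0.163, 0.195, 0.34 and 0.337) or vehicle 2 (0.134, 0.319, 0.388 and 0.388). Without 6-OHDA 1 Hsph1 in lymphatic (0.148) and Hspa1b in mesothelial cells (0.0734) were lost, and the latter without vehicle 3 (0.06). Lymphatic Hspa1b ranged from 19.7 to 1527 CPM in the 6-OHDA samples, and its log2 fold change from 2.66 to 6.42 with 1 sample left out. The heat shock count of types was 5 without 6-OHDA 3. The type I interferon response was higher in 7 types, with medians of 1.12 in neutrophils, 0.99 in monocytes and 0.89 in aerocyte capillary cells. It had 0 member calls by edgeR among 194 tests, and 19 when adjusted over the list alone, and the 7 types became 3 without 6-OHDA 2. The interferon gamma response was higher in 5 types, such as aerocyte capillary cells (0.69) and general capillary cells (0.68), and in 0 types without 6-OHDA 2 and 3 without vehicle 1. Genes of alternatively activated and lipid-associated macrophages were lower in 13 types (median -0.38), and in 5 types without 6-OHDA 1 and 7 without vehicle 2. Ribosomal proteins were lower in 13 types (-0.37). Median depth per cell was 2078 to 2223 transcripts in 6-OHDA and 1640 to 1906 in vehicle samples. Whether depth accounts for these ribosomal calls was not tested. Mitochondrially encoded genes were lower in 13 types (-0.36), and in 4 types without 6-OHDA 1 and 8 without vehicle 1 or vehicle 2. In alveolar macrophages the cell cycle genes were higher by 0.58.

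Alveolar macrophage markers were lower in 12 of 12 tested non-myeloid types under 6-OHDA without PDAC cells (median -0.84), and at -0.02 within alveolar macrophages. Non-myeloid types here leave out macrophages, monocytes, dendritic cells and neutrophils. The list of alternatively activated and lipid-associated macrophage genes holds some of the same genes, and the share of alveolar macrophages fell too.

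The comparison of BIBO3304 with vehicle without PDAC cells asks what blocking NPY1R changes in lung cells. Npas2 and Arntl, which encode activators of the circadian clock, were higher in 9 of 9 and 15 of 16 tested types. They were called in alveolar fibroblasts and alveolar type 2 cells. Npas2 was also higher in 8 of 9 types in vehicle-PDAC against vehicle samples, without the drug. Collection times are not given in the sources used here, so treatment and time cannot be told apart. In alveolar fibroblasts Npas2 reached 76.4 ± 28.2 CPM against 14.3 ± 6.79 (SD, n = 3 each; log2 fold change 2.28 ± 0.369, SE, adjusted p = 0.00708), and Arntl rose by 1.501 ± 0.290 (102 ± 18.3 against 34.8 ± 9.10 CPM, adjusted p = 0.0218). In alveolar type 2 cells the values were 1.75 ± 0.326 (adjusted p = 0.017) and 1.26 ± 0.291 (0.0376). Mt2, a metallothionein gene, fell in alveolar fibroblasts from 258.5 ± 40.1 to 94.1 ± 29.9 CPM (-1.46 ± 0.198, adjusted p = 0.00457), and Gsg1l rose there by 1.37 ± 0.218 (37.0 ± 1.10 against 13.7 ± 4.02 CPM, adjusted p = 0.00708). The chemokine gene Ccl6 fell in alveolar type 2 cells (-1.76 ± 0.290, 18.4 ± 4.95 against 64.8 ± 14.2 CPM, adjusted p = 0.00944). Chil3, a gene of alveolar macrophages, was lower too over all other cells, at 34.3 to 84.5 CPM in BIBO3304 samples and 136 to 142 CPM in vehicle samples. Whether the fall of Ccl6 arose in the alveolar type 2 cells themselves was not tested. Tox fell in B cells (-2.42 ± 0.466, 19.5 ± 15.8 against 97.7 ± 43.2 CPM, adjusted p = 0.0325). For Npas2, Arntl, Mt2, Gsg1l, Ccl6 and Tox in these types, all 3 BIBO3304 samples lay on 1 side of all 3 vehicle samples.

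Under BIBO3304 without PDAC cells 349 genes passed in 11 of 19 types, 91 higher and 258 lower among 113537 tests by edgeR. Alveolar fibroblasts held 156 (70 higher, 86 lower), alveolar type 2 cells 129 (10 higher, 119 lower) and B cells 21, all lower. Alveolar macrophage markers were lower too in 11 of 12 tested non-myeloid types (median -1.24). Whether the falls in alveolar type 2 and B cells arose in those cells was not tested. The count was 189, 23 (12 higher, 11 lower) and 712 without BIBO3304 1, 2 and 3, and 66, 25 and 101 without vehicle 1, 2 and 3. Of the 20 genes named by the fixed rule, 7, 4 and 18 stayed past the threshold without BIBO3304 1, 2 and 3, and 9, 3 and 10 without vehicle 1, 2 and 3. Npas2, Gsg1l and Mt2 in alveolar fibroblasts stayed past it in every such fit. Npas2 in alveolar type 2 cells was lost without BIBO3304 1 (adjusted p = 0.062), vehicle 1 (0.0591), vehicle 2 (0.0611) or vehicle 3 (0.071). The Ccl6 call was lost without BIBO3304 1 (0.0609), BIBO3304 2 (0.063) or vehicle 2 (0.0571), and the Tox call without BIBO3304 1 (0.152), BIBO3304 2 (0.371) or vehicle 2 (0.272). Arntl in alveolar fibroblasts was lost without any sample but BIBO3304 1 (0.0511 to 0.126), and in alveolar type 2 cells without any but BIBO3304 3 (0.0976 to 0.146).

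The same lists were tested under BIBO3304 without PDAC cells. Of 372 list tests 159 passed by camera, 27 higher and 132 lower. With an estimated correlation 0 passed, with a smallest adjusted p of 0.25 and 51 unadjusted p under 0.05, and fry passed 3. By camera, ribosomal proteins were lower in 19 of 19 types, with a median of -0.76 over the type medians. Of 1146 tests of members 32 passed, and 402 when adjusted over the list alone. An example is Rps12 in aerocyte capillary cells, at 162 against 597 CPM (-1.78 ± 0.359, adjusted p = 0.0181), lost without BIBO3304 2 (0.231), vehicle 1 (0.0851) or vehicle 2 (0.18). Oxidative phosphorylation genes were lower in 18 of 18 types (-0.65; 5 of 335 member tests, and 63 adjusted over the list alone), among them Cox6c in alveolar type 2 cells (-1.28 ± 0.254, adjusted p = 0.018), lost without any sample but BIBO3304 3 (up to 0.146, without BIBO3304 2). Those 18 types became 11 without BIBO3304 2. Mitochondrially encoded genes were lower in 16 types (-0.55; 9 of 166, and 61 adjusted over the list alone), with mt-Nd1 in alveolar fibroblasts at 67.1 ± 13.7 against 136 ± 13.7 CPM (-1.02 ± 0.151, adjusted p = 0.00543). Immediate early genes were lower in 13 types (-0.40; 13 of 375, and 82 adjusted over the list alone). The AP-1 genes Jund (483 ± 171 against 1105 ± 240 CPM, -1.19 ± 0.232, adjusted p = 0.0218) and Junb (-0.99 ± 0.190, adjusted p = 0.0214) fell in alveolar fibroblasts. Both were lost without BIBO3304 2 (0.0763 and 0.0957) or vehicle 2 (0.127 each), and Jund was lost without vehicle 3 too, at 0.05. The median depth per cell of these BIBO3304 samples was above that of each vehicle sample.

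Genes of alternatively activated and lipid-associated macrophages were lower under BIBO3304 in 16 types (-0.72; 5 of 228 member tests, and 60 adjusted over the list alone), such as Fabp4 in alveolar type 2 cells (1.98 against 14.2 CPM, adjusted p = 0.017) and Cd9 in B cells (55.3 against 206 CPM, adjusted p = 0.0367). Both calls were lost without any sample but BIBO3304 3, with adjusted p of up to 0.146 and 0.393, each without BIBO3304 2. Alveolar macrophage markers were lower in 11 of 12 tested non-myeloid types (median -1.24) and at 0.07 within alveolar macrophages, whose share fell. NF-kB inflammatory genes were lower in 9 types and chemokines in 7, with Cxcl1 in alveolar fibroblasts at 50.2 against 86.9 CPM (-0.80, adjusted p = 0.0263), lost without BIBO3304 2 (0.0919), vehicle 1 (0.0529), vehicle 2 (0.126) or vehicle 3 (0.085). The type I interferon response was higher in 6 types, with a median of 1.18 in neutrophils, and in 3 types without BIBO3304 2 and 4 without BIBO3304 3. Heat shock genes were higher in 12 types (0.34; 1 of 228 member tests, and 21 adjusted over the list alone). That heat shock count was 8, 4, 6 and 8 without BIBO3304 2, BIBO3304 3, vehicle 1 and vehicle 2. These list calls too were lost with an estimated correlation.

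The comparison of PDAC cells with none under vehicle asks what the seeded cells change. Tef, a clock-controlled transcription factor gene, was lower in 10 of 10 tested types. It was called in alveolar fibroblasts, at 18.8 ± 2.24 CPM (SD, n = 2) against 59.9 ± 10.6 (n = 3, log2 fold change -1.67 ± 0.254, SE, edgeR adjusted p = 0.0403). The call was lost without vehicle-PDAC 1 (0.867), vehicle 2 (0.187) or vehicle 3 (0.289). Scgb1a1, the secretoglobin gene of club cells, passed in ciliated cells (4.73 ± 0.638, adjusted p = 3.94e-05), at 1832 ± 2377 against 75.3 ± 49.4 CPM. Without vehicle-PDAC 2 its log2 fold change was 1.12 (adjusted p = 0.947). In that sample Scgb1a1 reached 81.7 CPM over all cells other than club cells, against 15.4 in vehicle-PDAC 1 and 8.66 to 31.6 in the other samples. These 2 genes were the calls, with 5571 unadjusted p under 0.05 and 62 calls by DESeq2. The next genes did not pass, among them Rnf144a in alveolar fibroblasts (1.25, adjusted p = 0.0779) and Hspa1a in aerocyte capillary cells (0.0737). The count was 12 and 122 without vehicle-PDAC 1 and 2, and 4 and 1 without vehicle 2 and 3.

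Heat shock genes were lower with PDAC cells under vehicle in 11 of 19 types (median -0.47), with 0 member calls by edgeR and 12 adjusted over the list alone. The heat shock count of types was 7 without vehicle-PDAC 1 and 2 without vehicle 3. The type I interferon response was higher in 3 types, with a median of 0.82 in dendritic cells. Immediate early genes were lower in 9 types (-0.21), and in 1, 17 and 3 types without vehicle-PDAC 1, vehicle-PDAC 2 and vehicle 2. In alveolar fibroblasts extracellular matrix genes (0.35) and inflammatory fibroblast genes (0.60) were higher, the latter not without vehicle-PDAC 1 (adjusted p = 0.223), and inflammatory fibroblast genes were lower in interstitial macrophages (-0.56). Ribosomal proteins were lower in 10 types (-0.20), and in 0, 19 and 4 types without vehicle-PDAC 1, vehicle-PDAC 2 and vehicle 2. Without vehicle-PDAC 1 they were higher in 8 types, so the direction turned. Of 372 list tests 52 passed by camera, 13 higher and 39 lower, and the count was 131 without vehicle-PDAC 2. With an estimated correlation 0 passed, with a smallest adjusted p of 0.892 and 17 unadjusted p under 0.05, and fry passed 1. Median depth per cell was 2411 to 3411 transcripts in vehicle-PDAC and 1640 to 1906 in vehicle samples. Its part in the ribosomal calls was not tested.

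**Figure D2:**
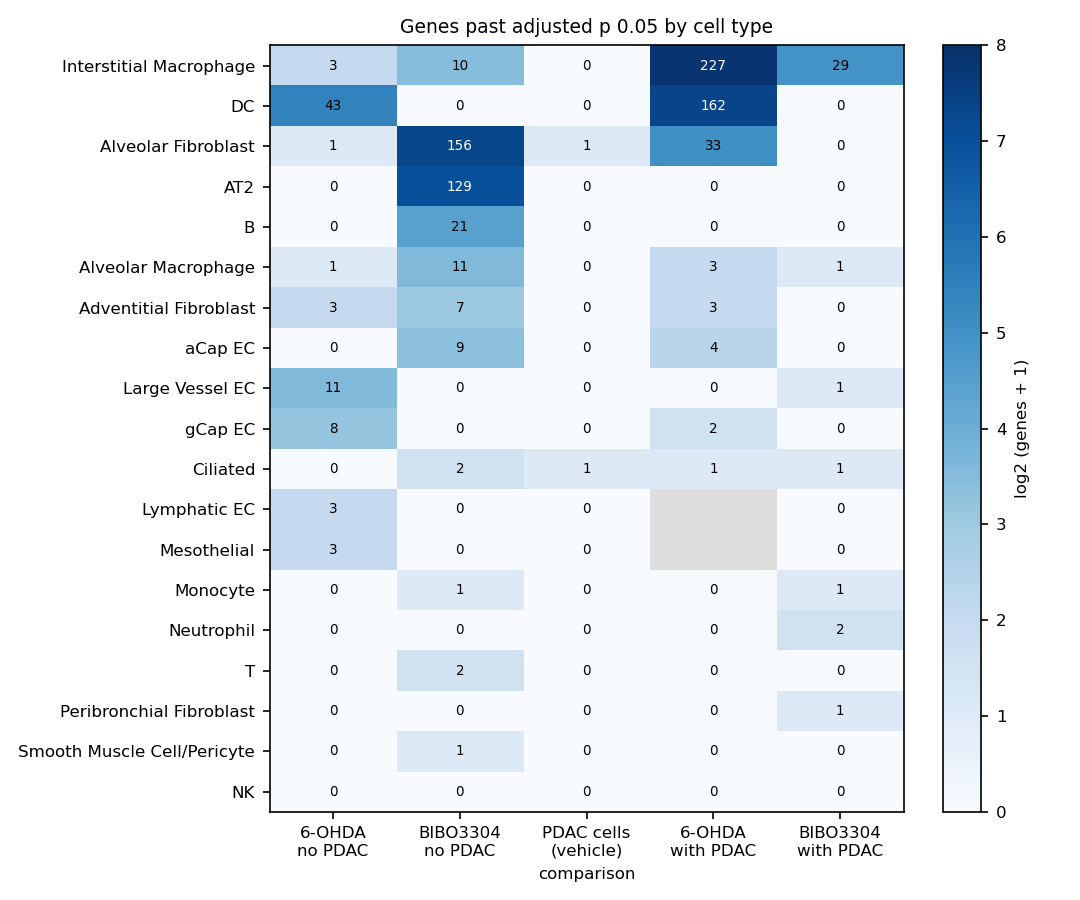
Number of genes past an adjusted p of 0.05 in each cell type (rows) and comparison (columns), coloured by log2 of the number plus 1, with grey for types not tested. Interstitial macrophages held 227 under 6-OHDA with PDAC cells, and alveolar fibroblasts held 156 under BIBO3304 without them.

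The comparison of 6-OHDA with vehicle when PDAC cells were seeded asks what the toxin changes in these lungs. In interstitial macrophages Arg1 was seen as 160 of 3344437 transcripts under 6-OHDA and 1 of 1947952 under vehicle, a ratio of 93.2 (counting interval 16.5 to 3704), or 46.6 ± 2.49 against 0.731 ± 1.03 CPM (SD, n = 2 each, edgeR adjusted p = 6e-04). Retnla, another gene of alternatively activated macrophages, fell there to 24.2 ± 4.30 from 365.5 ± 320.6 CPM (log2 fold change -3.90 ± 0.552, SE, adjusted p = 0.000341). The scavenger receptor genes Mrc1 and Cd163 were lower, by -2.14 ± 0.333 (366 ± 74.8 against 1617 ± 609 CPM, adjusted p = 0.00091) and -2.81 ± 0.5 (30.7 ± 19.3 against 222 ± 126 CPM, adjusted p = 0.00215). Cxcl9, an interferon-induced chemokine gene, rose to 67.3 ± 36.8 from 8.11 ± 9.41 CPM (2.86 ± 0.702, adjusted p = 0.0228). In dendritic cells H2-Ob, an MHC class II gene of B cells and dendritic cells, fell (-2.52 ± 0.478, 11.8 ± 9.53 against 76.7 ± 17.6 CPM, adjusted p = 0.00551). Ly6d rose there (3.14 ± 0.756, 45.0 ± 6.30 against 4.88 ± 0.0853 CPM, adjusted p = 0.0239). In alveolar fibroblasts Npas2 fell (-2.43 ± 0.460, 13.1 ± 3.36 against 70.0 ± 37.1 CPM, adjusted p = 0.037) and Tef rose (1.37 ± 0.270, adjusted p = 0.0393). Npas2 was lower in 7 of 8 tested types and Tef higher in 9 of 9.

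The interstitial macrophage type lost markers of more than 1 kind of cell under 6-OHDA with PDAC cells while its share rose. Alveolar macrophage markers within it had a median of -2.26 (7 genes, 3 called lower), conventional dendritic cell markers of the Cd209a kind -1.59 (6 genes, 3 called lower) and its own fixed markers -0.67 (9 genes, 2 called lower). Classical monocyte markers had a median of 0.03. Within the dendritic cells, plasmacytoid markers, which include Ly6d, had a median of 1.47 (0.87 to 3.14, 4 of 6 genes called higher). Without PDAC cells Slc6a2 in adventitial fibroblasts showed no fall, at 6.44 to 12.8 CPM in 6-OHDA samples and 5.59 to 12.7 CPM in vehicle samples, without TMM scaling. With them it was seen there as 0 of 1079827 transcripts under 6-OHDA and 117 of 4717668 under vehicle (27.1 and 22.4 CPM). The gene was at least 8.93-fold lower with a floor of 3 transcripts over the 6-OHDA group (adjusted p = 0.00449). It was chosen after its values were seen, and the call was lost without 6-OHDA-PDAC 1 (0.108) or 2 (0.105).

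For 6-OHDA with PDAC cells 435 genes passed in 8 of 17 types, 123 higher and 312 lower among 107528 tests by edgeR. Interstitial macrophages held 227 (21 higher, 206 lower), dendritic cells 162 and alveolar fibroblasts 33. The count was 220 and 35 without 6-OHDA-PDAC 1 and 2, and 671 without vehicle-PDAC 1. Of the 24 genes named by the fixed rule, 12 and 3 stayed past the threshold without 6-OHDA-PDAC 1 and 2, and 13 without either vehicle-PDAC sample. Arg1, Retnla and Slco2b1 in interstitial macrophages stayed past it in every such fit. Cxcl9 was lost without 6-OHDA-PDAC 2 (adjusted p = 0.371) or vehicle-PDAC 2 (0.199), and Cd163 and H2-Ob without 6-OHDA-PDAC 2 (0.083 and 0.113). Tef and Ly6d were lost without any 1 of the 4 samples, with adjusted p of up to 0.357 and 0.341. Npas2 was lost without 6-OHDA-PDAC 1 (0.298), 6-OHDA-PDAC 2 (0.403) or vehicle-PDAC 1 (0.157).

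Of 343 list tests under 6-OHDA with PDAC cells 57 passed by camera, 31 higher and 26 lower, and the count was 121 and 91 without vehicle-PDAC 1 and 2. With an estimated correlation 0 passed, with a smallest adjusted p of 0.518 and 31 unadjusted p under 0.05, and fry passed 0. By camera, heat shock genes were higher in 15 of 17 types (median 0.83), with 8 of 207 member tests called and 97 when adjusted over the list alone. Hspa1b rose in dendritic cells (4.16 ± 0.848, 168 ± 6.00 against 9.38 ± 3.04 CPM, adjusted p = 0.00809), interstitial macrophages (4.61 ± 1.15, adjusted p = 0.0246) and aerocyte capillary cells (3.91 ± 0.745, adjusted p = 0.0189). Without 1 sample the highest adjusted p of Hspa1b in these types were 0.125, 0.155 and 0.159. The interferon gamma response was higher in 5 types, with medians of 0.76 in interstitial macrophages and 0.69 in monocytes. Gbp2 rose in interstitial macrophages (1.86 ± 0.459, 58.6 against 16.2 CPM, adjusted p = 0.0233) as 1 of 4 member calls, with 8 adjusted over the list alone, and the 5 types became 3 without 6-OHDA-PDAC 2. The Gbp2 call was lost without 6-OHDA-PDAC 1 (0.106), 6-OHDA-PDAC 2 (0.229), vehicle-PDAC 1 (0.0783) or vehicle-PDAC 2 (0.103). The type I interferon response was higher in 4 types, such as dendritic cells (0.87), and in 2 without 6-OHDA-PDAC 2. MHC class II genes were lower in dendritic cells (-0.89), where plasmacytoid markers rose (median 1.47), and higher in neutrophils (0.76). They were higher in 0 types without 6-OHDA-PDAC 1 or vehicle-PDAC 1 and in 4 without vehicle-PDAC 2, and lower in 2 without vehicle-PDAC 1. NF-kB inflammatory genes were lower in 4 types, with -0.89 in interstitial macrophages, where Bcl3 (-1.59 ± 0.310, adjusted p = 0.00409) and the monocyte chemokine gene Ccl2 (-1.21 ± 0.260, 34.9 against 82.0 CPM, adjusted p = 0.0096) fell. Bcl3 was lost without 6-OHDA-PDAC 2 (0.154), and Ccl2 without 6-OHDA-PDAC 1 (0.112), 6-OHDA-PDAC 2 (0.167) or vehicle-PDAC 2 (0.169). That NF-kB inflammatory count was 1 without 6-OHDA-PDAC 2 and 8 without vehicle-PDAC 1.

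Genes of alternatively activated and lipid-associated macrophages were lower under 6-OHDA with PDAC cells in 9 types (-0.75), and in 17 and 0 types without vehicle-PDAC 1 and 2. Alveolar macrophage markers were lower in 10 of 10 tested non-myeloid types (-1.31) and at -0.29 within alveolar macrophages. These list calls too were lost with an estimated correlation. Ribosomal proteins were called in 0 types by camera, but without vehicle-PDAC 1 they were lower in 13 and without vehicle-PDAC 2 higher in 15. Median depth per cell was 3411 transcripts in vehicle-PDAC 1 and 2411 in vehicle-PDAC 2.

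The comparison of BIBO3304 with vehicle when PDAC cells were seeded asks what NPY1R block changes in these lungs. In interstitial macrophages Retnla fell to 35.5 ± 26.8 from 365.5 ± 320.6 CPM (SD, n = 2 each; log2 fold change -3.25 ± 0.553, SE, edgeR adjusted p = 0.00906). AA467197 rose there (2.59 ± 0.422, 62.1 ± 17.5 against 9.82 ± 5.61 CPM, adjusted p = 0.00906), as did the chaperone gene Hspe1 (2.12 ± 0.388, 52.9 ± 7.23 against 12.2 ± 3.38 CPM, adjusted p = 0.0138) and the matrix protease gene Mmp14 (1.62 ± 0.351, 119 ± 5.64 against 36.8 ± 27.3 CPM, adjusted p = 0.036). In neutrophils the mitochondrial carrier gene Sfxn5 fell (-2.31 ± 0.412, 82.2 ± 10.1 against 408 ± 44.6 CPM, adjusted p = 0.0224), and Sgms2, a sphingomyelin synthase gene, changed by -1.71 ± 0.328 (adjusted p = 0.0311). Cxcl9 in interstitial macrophages did not pass (3.13 ± 0.714, adjusted p = 0.0505).

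For BIBO3304 with PDAC cells 36 genes passed in 7 of 19 types, 7 higher and 29 lower by edgeR, with 8806 unadjusted p under 0.05 and 406 calls by DESeq2. Interstitial macrophages held 29 of them and neutrophils 2. The count was 17 and 7 (6 higher, 1 lower) without BIBO3304-PDAC 1 and 2, and 118 and 108 without vehicle-PDAC 1 and 2. Of the 9 genes named by the fixed rule, 2 and 1 stayed past the threshold without BIBO3304-PDAC 1 and 2, and 6 and 2 without vehicle-PDAC 1 and 2, and none stayed past it in every such fit. Retnla was lost without BIBO3304-PDAC 1 (adjusted p = 0.117), BIBO3304-PDAC 2 (0.149) or vehicle-PDAC 2 (0.126). AA467197 was lost without BIBO3304-PDAC 2 (0.469) or vehicle-PDAC 2 (0.0823). Hspe1 was lost without any 1 of the 4 samples (0.0611 to 0.421), Mmp14 without BIBO3304-PDAC 1 (0.187), BIBO3304-PDAC 2 (0.469) or vehicle-PDAC 2 (0.23), and Sgms2 without BIBO3304-PDAC 1 (0.337) or vehicle-PDAC 1 (0.171). Sfxn5 was lost without BIBO3304-PDAC 1 (0.222), BIBO3304-PDAC 2 (0.164) or vehicle-PDAC 1 (0.146).

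Heat shock genes were higher under BIBO3304 with PDAC cells in 19 of 19 types (median 1.02; 2 of 228 member tests, and 128 adjusted over the list alone), and in 17 to 19 with 1 sample left out. Hspa8, a constitutive chaperone gene, rose in large-vessel endothelial cells (1.74 ± 0.296, 626 against 192 CPM, adjusted p = 0.0119), a call lost without BIBO3304-PDAC 1 (0.604), vehicle-PDAC 1 (0.576) or vehicle-PDAC 2 (0.0684). The interferon gamma response was higher in 5 types, with 0.99 in interstitial macrophages, and in 8, 3 and 3 types without BIBO3304-PDAC 1, BIBO3304-PDAC 2 and vehicle-PDAC 1. Genes of the type I interferon response were higher in 4 types, with 0.82 in dendritic cells, and in 2 without BIBO3304-PDAC 2. In dendritic cells the plasmacytoid marker Ccr9 was at 95.1 and 77.55 CPM in BIBO3304-PDAC and 25.3 and 46.1 CPM in vehicle-PDAC samples. It was chosen after its values were seen, 0 genes were called in that type, and a changed mix of dendritic cells was not tested. MHC class II genes were higher in 3 types (neutrophils 1.12, alveolar fibroblasts 0.77, alveolar macrophages 0.74) and lower in dendritic cells (-0.70). The 3 types became 7, 1 and 7 without BIBO3304-PDAC 1, BIBO3304-PDAC 2 and vehicle-PDAC 2. NF-kB inflammatory genes were lower in interstitial macrophages (-0.53). Ribosomal proteins were higher in 19 types (0.59; 0 member calls by edgeR, and 6 adjusted over the list alone), and in 11 and 5 without BIBO3304-PDAC 2 and vehicle-PDAC 1. Those samples had the lowest and highest median depth per cell of the 4 (1623 and 3411 transcripts), with 0.981% and 0.347% of alveolar fibroblast transcripts from ribosomal protein genes. Oxidative phosphorylation genes were higher in 10 types (0.45), and in 1, 0 and 18 without BIBO3304-PDAC 2, vehicle-PDAC 1 and vehicle-PDAC 2. Of 372 list tests 84 passed by camera, 75 higher and 9 lower, and the count was 53 without BIBO3304-PDAC 2 and 147 without vehicle-PDAC 2. With an estimated correlation 0 passed, with a smallest adjusted p of 0.621 and 19 unadjusted p under 0.05, and fry passed 0.

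**Figure D3:**
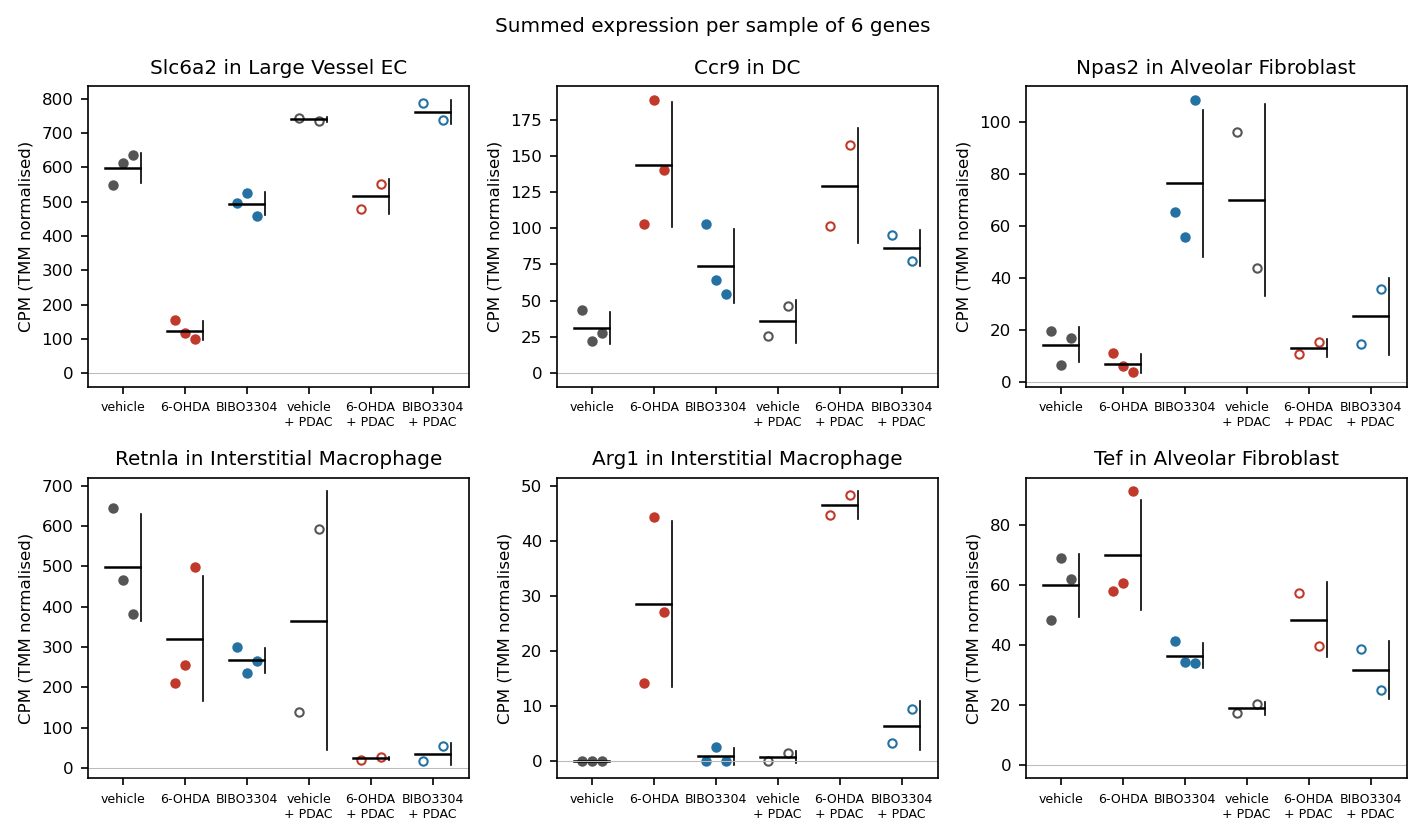
Expression per sample in CPM (y axis) of 6 genes in the cell type named above each panel, by group (x axis), with a point per sample. Slc6a2 in large-vessel endothelial cells was 98.96 to 156 CPM in the 6-OHDA samples and 549.5 to 635 CPM in the vehicle samples.

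Interaction tests asked whether a drug's effect differed with PDAC cells. For 6-OHDA 8 genes passed, all with negative values. A negative value means a log2 fold change lower with PDAC cells than without them, which need not be a weaker effect. Among them were Colq in alveolar fibroblasts (-1.86 ± 0.280, adjusted p = 0.0339) and Il1rap in dendritic cells (-3.26, adjusted p = 0.00482), which was chosen after its values were seen. For BIBO3304 469 genes passed, 289 higher and 180 lower, with 131 in B cells, 95 in alveolar fibroblasts and 84 in alveolar type 2 cells. In alveolar fibroblasts the interaction was -3.99 for Npas2 (adjusted p = 0.00665), -2.56 for Arntl (0.018) and 2.85 for Mt2 (0.000372). The 6-OHDA count was 3 and 0 without 6-OHDA-PDAC 1 and 2, 3, 22 and 3 without 6-OHDA 1, 2 and 3, 73 and 9 without vehicle-PDAC 1 and 2, and 2, 2 and 4 without vehicle 1, 2 and 3. The direction turned without vehicle-PDAC 2 (6 of 9 higher, 1 shared with the 8) and without 6-OHDA 1 (2 of 3 higher). The BIBO3304 count was 37 without BIBO3304-PDAC 2, 181, 111 and 1045 without BIBO3304 1, 2 and 3, 155 and 4285 without vehicle-PDAC 1 and 2, and 263, 56 and 284 without vehicle 1, 2 and 3. More of these calls were lower than higher without BIBO3304-PDAC 2 (20 against 17), BIBO3304 1 (94 against 87), BIBO3304 2 (67 against 44), vehicle-PDAC 1 (106 against 49) and vehicle 2 (39 against 17).

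**Figure D4:**
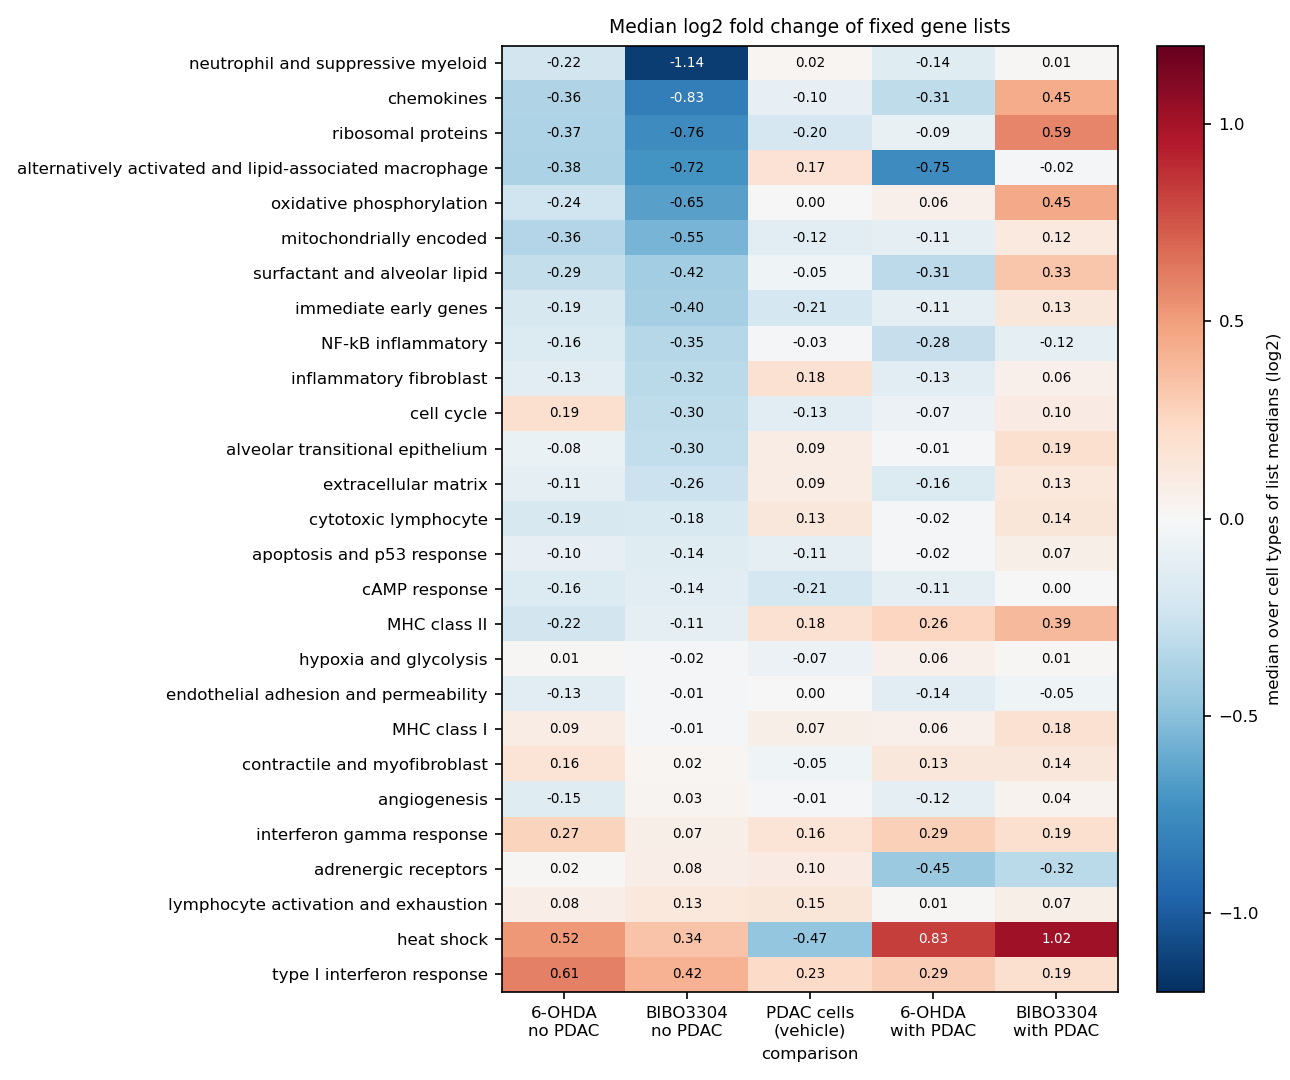
Median over cell types of the median log2 fold change of each fixed gene list (rows) in each comparison (columns). Ribosomal proteins stood at -0.76 under BIBO3304 without PDAC cells and at 0.59 under BIBO3304 with them, and heat shock genes at 1.02 under BIBO3304 with PDAC cells.

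The NPY and adrenergic receptor genes were read in each type where they reached a mean of 20 CPM. Npy1r was highest in smooth muscle cells and pericytes, at 42.6 CPM with a transcript in 6.15% of cells, and reached 11.6 CPM in mesothelial cells. Adra1a, the alpha-1A adrenergic receptor gene, was at 478.5 CPM in alveolar fibroblasts, with a transcript in 50.2% of cells. Alveolar macrophages had a transcript of Npy1r in 0.0466% and of Adra1a in 1.38% of cells, at a median depth of 2932 transcripts against 1508 in smooth muscle cells and pericytes and 2653.5 in alveolar fibroblasts. Adrb1 was at 83.0 CPM in general capillary cells and 40.3 CPM in alveolar macrophages. In 104 tests of 21 pairs of gene and type, 0 passed by edgeR, 18 had an unadjusted p under 0.05 and 2 passed by DESeq2. These tests include Dpp4, a peptidase gene on the NPY list, at 252 CPM in mesothelial cells and 187 CPM in alveolar type 2 cells. Npy1r did not pass the gene filter in smooth muscle cells and pericytes, so its response to the drugs was not tested there. Adra1a in alveolar fibroblasts did not pass under BIBO3304 without PDAC cells (0.66 ± 0.177, SE, adjusted p = 0.0713) or with them (-0.76 ± 0.221, 0.239), nor under 6-OHDA with them (-0.71 ± 0.218, 0.218), against the same vehicle-PDAC samples. Its BIBO3304 interaction passed (-1.42, adjusted p = 0.0307).

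The effects of both drugs were set side by side, since each is meant to interrupt sympathetic signalling. Without PDAC cells the log2 fold changes of 6-OHDA and BIBO3304 had a median correlation across genes of 0.5945 over 19 types (0.4105 to 0.69). Simulated unchanged groups against the same vehicle samples gave 0.5011, since the comparisons share those samples, and genes are not independent replicates. With PDAC cells the median was 0.3681 over 17 types (0.2102 to 0.7682), against 0.4984 in the simulations. Interstitial macrophages (0.7682), dendritic cells (0.6338) and monocytes (0.5232) lay above their highest simulated values (0.525, 0.5136 and 0.5173). Without PDAC cells most types did so too, such as alveolar type 2 cells (0.69 against 0.5119), while others did not, such as mesothelial cells (0.4105 against 0.5435). The simulations drew each gene independently, while real genes can move together. Lying above a highest simulated value therefore does not show a shared effect of the drugs. Gsg1l in alveolar fibroblasts and Gm15459 in alveolar macrophages were the 2 calls that both drugs raised without PDAC cells, and 0 were lowered by both. With PDAC cells 25 calls were lowered by both drugs and 3 raised, all in interstitial macrophages. That type held a mixed signal, and under 6-OHDA with PDAC cells it lost markers of several kinds of cell. These shared calls include Retnla. All of them rest on the same 2 vehicle-PDAC samples, which makes shared calls more frequent, and no overlap was simulated.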

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

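The test with a gene-span trend was chosen only after the result was seen. The difference between a drug's effects with and without PDAC cells was tested as an interaction. For 6-OHDA 8 genes passed, among them Colq in alveolar fibroblasts (-1.86, adjusted p = 0.0339) and Slc6a2 in adventitial fibroblasts (-8.17, adjusted p = 0.0373). The Slc6a2 value depends on the prior count, since 6-OHDA-PDAC samples held 0 transcripts. For BIBO3304 469 genes passed. Values follow for those among them that the naming rule took from a drug or PDAC comparison or that were chosen after their values were seen. In alveolar fibroblasts the values were -3.99 for Npas2 (adjusted p = 0.00665), -2.56 for Arntl (0.018), 1.55 for Tef (0.0473), 2.85 for Mt2 (0.000372), 2.05 for Arf5 (0.0122), 1.46 for Junb (0.0342), 1.04 for mt-Nd1 (0.0487) and -1.42 for Adra1a (0.0307). In alveolar type 2 cells they were -2.99 for Npas2 (0.0198), -2.53 for Arntl (0.0241), 2.40 for Ccl6 (0.0214), 2.15 for Cox6c (0.0214), 4.22 for Fabp4 (0.0279) and 3.04 for Srgn (0.0349). In B cells they were 3.14 for Tox (0.0313), 3.98 for Pygl (0.0386), 3.41 for Cd300a (0.0484), 3.21 for Cox5a (0.0262) and 5.89 for ENSMUSG00000120878 (0.0245). In interstitial macrophages they were 3.04 for AA467197 (0.036), 2.53 for Hspe1 (0.0328) and -2.84 for Plxna4 (0.0108), and in neutrophils -2.84 for Sfxn5 and -2.33 for Sgms2 (0.00726 each). Under BIBO3304 alveolar macrophage markers in 12 non-myeloid types had a median of -1.24 without PDAC cells and -0.09 with them. Whether the interactions in alveolar type 2 and B cells arose in those cells was not tested. No group held 4 or more samples, so single samples far from their group were not tested.

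Among the BIBO3304 interaction genes are clock genes: Npas2 was higher in 9 of 9 types under BIBO3304 without PDAC cells and lower in 9 of 9 with them, and Tef went the other way in 10 of 10 types each. A clock index, the mean log2 level of Npas2, Arntl and Clock minus that of Dbp, Tef, Hlf, Per2, Per3, Nr1d1, Nr1d2 and Ciart, averaged 0.625 under BIBO3304, 0.832 in vehicle-PDAC, -0.391 under vehicle, -0.511 under 6-OHDA and -0.384 in 6-OHDA-PDAC, and the BIBO3304-PDAC samples stood at -0.45 and 0.363. Under BIBO3304 without PDAC cells 9 of 11 types other than alveolar fibroblasts and alveolar type 2 cells differed by more than 0.3, which is in line with a shift in all cells of a sample. Depth per cell went with the index over 15 samples (r = 0.582, permutation p = 0.0207, adjusted 0.0414 over 4 relations; rho = 0.50, p = 0.0608, adjusted 0.0811; r = 0.534 without the 2 farthest samples), but depth and groups go together here and no such relation was seen within groups (r = 0.0171, permutation p = 0.953), so depth stays open. Different times of day at collection may be the cause: group means spread 1.66 times as widely as samples within groups, yet collection times are not given in the sources used here, and treatment and time cannot be told apart.

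The ribosomal proteins list was lower by camera in 19 of 19 types under BIBO3304 without PDAC cells, with 32 of 1146 member tests past the threshold, and was lost in each type with an estimated correlation (smallest adjusted p = 0.337). A single deep library is argued against, since 18 of 19 types stayed lower without BIBO3304 2, with the median moving from -0.76 to -0.54. Depth per cell may contribute. In the 12 samples of the other groups the ribosomal share of alveolar fibroblast transcripts fell with depth (r = -0.655, permutation p = 0.0353, adjusted 0.0471). By rank rho was -0.594 (permutation p = 0.0443, adjusted 0.0811), and r was -0.636 without the 2 farthest samples. Within groups that share fell with depth too (r = -0.827, permutation p = 0.00133). That permutation treats deviations from group means as independent, which they are not, so its p can be too small. The share in other types was not tested against depth. A trend with gene span went the same way (median rho 0.247), and removing it moved the ribosomal median from -0.7586 to -0.2965, or 39.1% of its size. An effect of the drug on ribosomal transcripts stays open beside these, as untested.

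The 6 samples of each comparison without PDAC cells can be split in 10 ways, too few for a share under 0.05. The real split gave as large a result in 1 of 10 splits each time. For 6-OHDA the real split gave 76 genes, 110 list calls and 3 shares, and the highest other split gave 13, 70 and 0. For BIBO3304 it gave 349 genes, 159 list calls and 2 shares, and the highest other split gave 3, 127 and 0. Each other split mixes treated and vehicle samples in both groups. Part of any difference between treatments then enters the spread within groups, and part stays between the groups. The low gene and share counts of these splits are therefore not counts for unchanged samples. Nor do the 70 and 127 list calls show how many lists camera with the preset correlation would pass for unchanged samples.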

How the results depend on the processing

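The fit without the top Scrublet scores, and the list tests with a term for the sample number, were tests chosen only after seeing the data. RLE size factors kept every count within 1.5 times and left 115 of 120 named genes on their side of the threshold, and TMM over cell types left 8 of 8 shares. Other settings left 110 (no filter), 109 (sample number as a term) and 110 (top Scrublet scores) of 120, 113 of 113 (minimum of 50 cells), 72 of 113 (compared groups alone) and 84 of 102 (DESeq2). With 1 sample left out 280 of 621 values stayed, 335 lost their call, 5 gained one and 1 reversed, and 36 of 42 share calls stayed. The reversed value was Scgb1a1 in T cells for PDAC cells against none, -0.94 without vehicle-PDAC 2 (range -0.94 to 6.34). Directions turned in some settings. For 6-OHDA 57 of 76 calls were higher, against 250 of 641 without the filter and 84 of 195 with the compared groups alone. For BIBO3304 with PDAC cells 7 of 36 were higher, against 14 of 14 with the compared groups alone, which shared 2 calls with the 36, and for its interaction 289 of 469 against 37 of 95. With the sample number as a term, heat shock genes were lower in 3 types for PDAC cells against none, against 11, and ribosomal proteins in 7 against 10. With DESeq2 43.6% of BIBO3304 calls and 33.8% of its interaction calls were higher, where edgeR had 91 of 349 and 289 of 469. The median of all genes in the DESeq2 BIBO3304 interaction was 0.282.

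Counts that moved follow in the order 6-OHDA, BIBO3304, PDAC cells against none, 6-OHDA with PDAC cells, BIBO3304 with PDAC cells, 6-OHDA interaction and BIBO3304 interaction. Without the filter they were 641, 2831, 327, 1139, 618, 187 and 2558 genes, as genes with few counts enter the tests. With the compared groups alone they were 195, 761, 4, 343 (within 1.5 times), 14, 4 and 95, where the spread rests on fewer samples. With DESeq2 they were 210, 848, 62, 602 (within 1.5 times), 406, 67 and 1245, and the cause was not tested. A minimum of 50 cells and the top Scrublet scores each gave 4 for PDAC cells against none. For BIBO3304 with PDAC cells the sample number as a term gave 94 and the top Scrublet scores 63, and for BIBO3304 shares those scores gave 1, with club cells lost; the cause was not tested. List counts with an estimated correlation were 0, 0, 0, 0 and 0, and with fry 2, 3, 1, 0 and 0, and the cause was not tested.

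Leaving out each sample in turn, where a lone sample is assumed to vary like the other groups, gave ranges in the same order of 4 to 87, 23 to 712, 1 to 122, 35 to 671, 7 to 118, 0 to 73 and 37 to 4285 genes. List counts ranged from 75 to 105, 133 to 163, 38 to 131, 39 to 121 and 53 to 147. Shares ranged from 2 to 4, 2 to 3, 0 to 1, 2 to 3 and 0 to 1. The similarity of the drugs' effects was 0.5915 and 0.419 over genes above the median CPM, against 0.5945 and 0.3681. Sample numbers did not pair samples: 33 pairs of the same number had mean correlations of -0.00781 to 0.0168 in 4 types. The planned removal of Scrublet calls was not run, since it marked 32 cells, and the vehicle samples could not be split between the drugs. Exact permutation tests cannot reach 0.05 here, and with 2 samples per group few 2-fold changes were recovered in simulated data.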

Other observations

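The test of Slc6a2 with 1 library left out was chosen only after the result was seen. Alveolar macrophages carried cell cycle genes at a higher level under 6-OHDA by camera, both without PDAC cells (median 0.58) and with them (0.79), calls that stayed with any 1 sample left out but were lost with an estimated correlation (smallest adjusted p of any list 0.613 and 0.518). Mki67, chosen after its values were seen, was at 140 ± 45.5 CPM in alveolar macrophages under 6-OHDA and 51.4 ± 7.08 under vehicle (SD, n = 3 each). Its change did not pass (1.45 ± 0.237, SE, edgeR adjusted p = 0.0578), but passed without 6-OHDA 3 (0.00403). Under BIBO3304 without PDAC cells cell cycle genes were lower in T cells (-0.91), a call lost with an estimated correlation (smallest adjusted p of any list 0.25). The extracellular matrix list was lower in alveolar macrophages without PDAC cells under 6-OHDA (-0.72) and BIBO3304 (-0.64), calls also lost with an estimated correlation. With PDAC cells it was lower there under 6-OHDA too (-0.61), but not without 6-OHDA-PDAC 2 (adjusted p = 0.966) or vehicle-PDAC 2 (0.943).

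Inflammatory fibroblast genes were lower in alveolar fibroblasts under BIBO3304 without PDAC cells (-0.68). Genes of the neutrophil and suppressive myeloid list were lower there in B cells (-1.87) and alveolar type 2 cells (-1.70). Alveolar macrophage markers were lower too in 11 of 12 tested non-myeloid types (median -1.24), as was the share of those macrophages. In neutrophils under BIBO3304 with PDAC cells that list was lower (-0.74), but not without BIBO3304-PDAC 1 (adjusted p = 0.0716) or vehicle-PDAC 1 (0.0552). Chemokines were lower in neutrophils under 6-OHDA without PDAC cells (-0.98). In monocytes under BIBO3304 with PDAC cells they were higher (1.05), but not without BIBO3304-PDAC 2 (adjusted p = 0.27) or vehicle-PDAC 1 (0.182). The cAMP response was lower in aerocyte capillary cells under BIBO3304 without PDAC cells (-0.72). Its member Fosb, chosen after its values were seen, fell there from 1251 ± 346 to 583 ± 71.6 CPM (SD, n = 3 each; -1.08 ± 0.204, SE, edgeR adjusted p = 0.0126). That call was lost without BIBO3304 2 (0.122), BIBO3304 3 (0.113), vehicle 1 (0.113) or vehicle 2 (0.121). None of these list calls passed with an estimated correlation.

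The fall of Slc6a2 in large-vessel endothelial cells under 6-OHDA without PDAC cells (-2.26 ± 0.235, edgeR adjusted p = 7.32e-07) may follow from the toxin's entry through this transporter, a hypothesis not tested here, which 6-OHDA given with a blocker of the transporter would address. A loss of venous cells as the whole cause is argued against, since the other 7 venous markers tested had a median of -0.28 (Prss23 lowest, at -0.95), but arterial markers had a median of 1.03 (smallest adjusted p = 0.135, Gja5), so a partial shift from venous to arterial cells stays open. A single library is argued against too, as the highest adjusted p with 1 sample left out was 4.84e-05. A chance difference of those samples stays open, since with PDAC cells the difference of mean log2 CPM was -0.46, against -2.22 without them. The edgeR test with PDAC cells did not pass (-0.53 ± 0.239, adjusted p = 0.846), nor did the interaction (1.73 ± 0.339, unadjusted p = 1.8e-05, adjusted p = 0.105).

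The 4 cancer cells annotated in samples without PDAC cells held 553 to 771 transcripts each, against a median of 19624.5 for those in samples with PDAC cells. The 13 fixed markers of PDAC or ductal tumours were highest in cancer cells as a list (mean log2 excess 1.24, against 0.995 in club cells). Onecut2, Spp1, Sox9 and Lgals4 were highest in cancer cells, Tff1 had no transcript in any type, and the other 8 were higher in another type, such as Krt19 in club cells (168 against 56.3 CPM).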
